A study of Homo sapiens with 24 samples.

How the data were processed

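Gene expression was measured in CD14+ monocytes, the circulating phagocytes of human blood, from 4 healthy donors and 4 donors with multiple sclerosis (MS). Each donor gave 3 arrays, labelled as untreated control, a myelin isolate at 10 ug/ml, and the myelin isolate with bexarotene at 1 uM. The 24 samples therefore formed 6 groups of 4 arrays. Bexarotene is a drug that activates the retinoid X receptors (RXR), nuclear receptors that pair with many others. No arrays of bexarotene without myelin were analysed here.

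The authors deposited 1 table of log2 expression values, with a row for each of 33297 probe sets and a column for each array. Affymetrix Expression Console and RMA were used, per the submitters' processing notes, which give no version of either. RMA corrects the background of an Affymetrix array, normalizes the arrays by quantiles and summarises the probes of each probe set on the log2 scale. The deposited values ran from 2.12 to 14.4, and the medians of the arrays lay between 6.41 and 6.46. The genome build behind the probe sets is not given in the sources used here. No array pair held identical values, and correlations between arrays ran from 0.982 to 0.997. The precision of each value is limited by the number of arrays.

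Probe sets were named from the platform annotation given with the values, which can be old. Of the probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none listed. Names were checked through the Entrez identifier: 19429 probe sets matched a current gene, 31 kept the symbol of the annotation and 0 symbols changed. Y-linked genes and the X-inactivation genes were left out of every step, which removed 95 probe sets. For the 768 genes with more than 1 probe set, the probe set of highest mean over all arrays was taken, so probe sets of such a gene that differ were not averaged. A gene was tested where its value lay above the 40th percentile of its array in at least 4 arrays. That threshold was 5.80 to 5.87 on the log2 scale, and it kept 13081 of 18394 genes.

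Tests were run with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Treatment effects were within-donor contrasts with the donor as a fixed block, fitted on all 24 arrays (12 residual degrees of freedom, 6.9 added by eBayes). Comparisons of MS with healthy donors used the 6 group means with the donor as a random block (duplicateCorrelation, consensus correlation 0.56). That correlation was shared by all genes. Where donors differ more in a gene than it allows, the SE understates the spread between donors. The series' design text gives 4 sources per diagnosis under 3 conditions, so arrays with the same diagnosis and number came from 1 donor. The values were checked against this: the 24 pairs with the same number had residual correlations of at least 0.50 (median 0.70), the 72 other pairs reached at most 0.49 (median −0.25), and 24 of 24 arrays correlated best with their own number. Group means were subtracted first, which by itself draws the other pairs below 0, so their negative median is no part of the check. The bexarotene effect is the difference between myelin with bexarotene and myelin alone. An effect over all donors is the mean of the healthy and the MS effect with equal weight.

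Gene lists for 31 pathways, cell types and complexes were fixed before the data were examined. They covered targets of LXR, PPAR and the retinoic acid receptor, the RXR family and its partners, cholesterol synthesis, phagocytic receptors, the actin of the phagocytic cup, and the lysosome. Others covered NF-kappaB cytokines, the interferon response, antigen presentation, alternative activation, immediate early genes, heat shock, the unfolded protein response, oxidative stress, metallothioneins, glycolysis, oxidative phosphorylation, the cell cycle and the extracellular matrix. Marker lists covered monocytes, T, B and NK cells, platelets, neutrophils, erythroid cells, dendritic cells, oligodendrocytes, and neurons with astrocytes. Each list was tested with camera, with limma's preset correlation and with an estimated one, and with fry, adjusted over the lists. For comparisons of MS with healthy donors, the arrays were first transformed to remove the donor correlation. Camera compares a list with the other genes; fry tests whether the genes of a list move one way on balance. For each list, genes passing were counted over all genes tested and, in a second count, adjusted over the list alone.

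Genes named in the text were chosen by a rule fixed before the data were examined. It took the 8 largest increases and decreases of the myelin and the bexarotene effect over all donors, among genes that passed and moved the same way in every donor. It took 4 of each for myelin with bexarotene against control and up to 5 of each in the other comparisons, and from each list up to 4 members of smallest p. Where fewer than 5 genes passed, the 5 of smallest p were taken and are said not to pass. RXRA, RXRB, ABCA1 and ABCG1 belonged to the rule in every comparison. Genes whose level in one person can reflect genotype, such as HLA genes, were not named. Any gene named outside this rule was chosen after its values were seen, and the text says so.

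The fits were tested on simulated data with known changes, drawn for the same 13081 genes. Changes of 1 on the log2 scale were recovered for 100% of genes in the myelin and the bexarotene effect over all donors, and for 95.5% in the comparison of MS with healthy control arrays. Changes of 0.5 were recovered for 97%, 95.5% and 59.7% of genes in these comparisons. Unchanged genes made up 7% of the calls for myelin, 4.4% for bexarotene and 17.1% for MS against healthy control arrays, and with no change simulated the calls were 0, 0 and 6. For the difference of an effect between diagnoses, recovery at 0.5 was 76.1% for myelin and 67.2% for bexarotene.

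Alternatives were a fit without the donor block, the donor as a random block, and only the arrays compared or of that diagnosis. Further ones were no filter or a filter at the 60th percentile (9010 genes), centring or quantile normalization again, all probe sets on their own (21050), eBayes with trend and robust, array weights, and each donor left out in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and figures. The sources used here name no collection, culture or array batch, so no batch was tested.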

Results

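Gene expression arrays were made from CD14+ blood monocytes of 4 healthy donors and 4 donors with multiple sclerosis, an inflammatory disease in which the myelin around nerve fibres is lost. Monocytes of each donor were kept as control, given a myelin isolate at 10 ug/ml, or given the isolate with bexarotene at 1 uM, which gave 6 groups of 4 arrays. Bexarotene activates the retinoid X receptors, nuclear receptors that bind DNA together with partners such as LXR, PPAR and the retinoic acid receptors. The deposited log2 values had array medians of 6.41 to 6.46, and the number of arrays limits the precision. The comparisons ask what myelin does to monocytes, what retinoid X receptor activation adds, and whether MS monocytes then come closer to healthy ones. Changes below are log2 differences ± SE with adjusted p-values from limma over 13081 genes.

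The main axes of variance differed by diagnosis and by bexarotene. The first principal component took 27.6% of the variance and the second 18.2%. MS control arrays had a mean of 17.4 ± 5.0 (SD, n = 4) on the first, against −8.2 ± 7.2 (SD, n = 4) for healthy controls. Bexarotene lowered the first component too, from a mean of 16.2 ± 5.8 with myelin alone to 4.6 ± 6.6 in MS donors and from −8.8 ± 9.0 to −21.2 ± 6.0 in healthy donors, so this component did not stand for diagnosis alone. With bexarotene the mean on the second component was −11.3 ± 0.9 (SD, n = 4) in healthy and −19.9 ± 3.5 (SD, n = 4) in MS donors, against 12.2 ± 1.3 and 2.3 ± 1.5 with myelin alone.

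**Figure D1:**
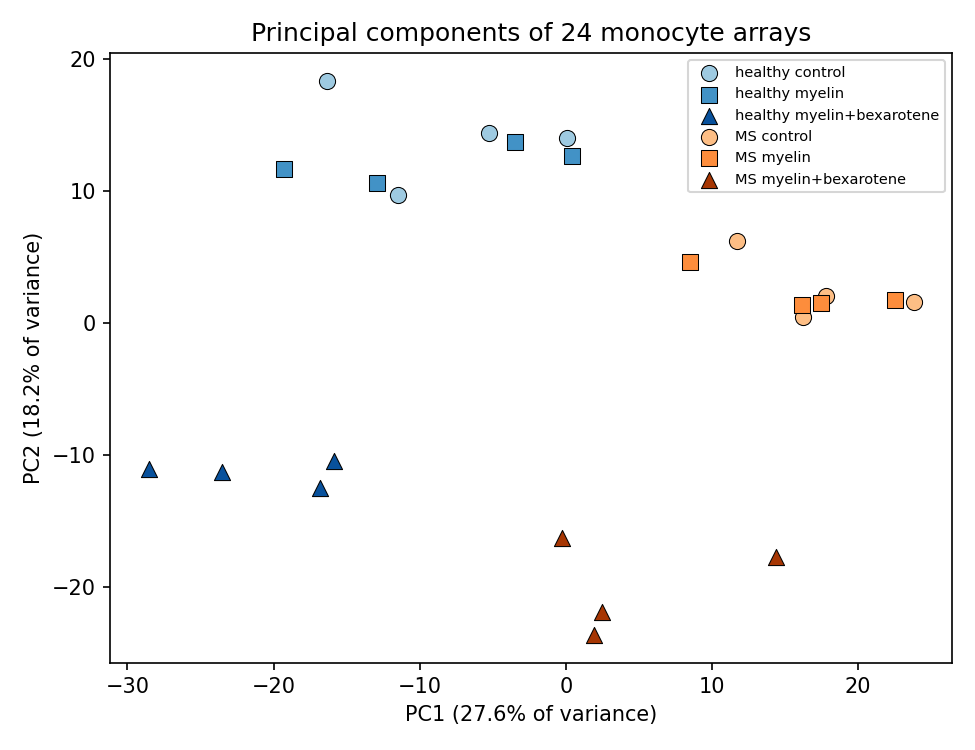
Position of each of the 24 arrays on the first component (27.6% of variance) and the second (18.2%), with colour for diagnosis and treatment and shape for treatment. Arrays with bexarotene lie below 0 on the second component in both diagnoses, and control and myelin arrays of a diagnosis lie together.

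The myelin isolate raised MBP, MOBP, DAB2, CTSL and MRC1. MBP, which encodes myelin basic protein, rose by 1.00 ± 0.06 (adjusted p = 4.1e-08) and MOBP, another myelin protein gene, by 0.53 ± 0.07 (0.00022), each in 8 of 8 donors. DAB2, an adaptor for clathrin-coated uptake, rose by 0.97 ± 0.08 (6.6e-07), and CTSL, the lysosomal protease cathepsin L, by 0.61 ± 0.08 (0.00017), again in 8 of 8. MRC1, the mannose receptor, rose by 0.77 ± 0.15 (0.017) in 7 of 8 donors, and did not pass without healthy replicate 2 (adjusted p = 0.078), healthy replicate 4 (0.062) or MS replicate 2 (0.056), with the donor as a random block (0.06) or with trend and robust eBayes (0.11). The largest increase was TARP, a transcript of the T cell receptor gamma locus, at 1.47 ± 0.19 (0.00017). Whether its probe set measured TARP or another transcript of the locus is not settled here, and the 12 T cell markers had a median change of 0.00.

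In all, 50 genes rose with myelin and 1 fell, and 855 genes had an unadjusted p under 0.05 against 654 that chance gives. The fall was FLJ42627, an uncharacterised transcript, at −0.17 (adjusted p = 0.024). It did not pass without healthy replicate 1 (0.11), healthy replicate 2 (0.16), healthy replicate 3 (0.08), MS replicate 1 (0.12), MS replicate 2 (0.065), MS replicate 3 (0.076) or MS replicate 4 (0.11), nor with a random block (0.87). Other increases were EMP1 (0.84 ± 0.09), CISH, an inhibitor of cytokine signalling (0.83 ± 0.12), the glutamyltransferase GGT5 (0.80 ± 0.07), the coenzyme Q enzyme PDSS1 (0.71 ± 0.07), and NDUFV2, a subunit of respiratory complex I (0.66 ± 0.06). IL3RA, an interleukin-3 receptor chain on the dendritic cell list, rose by 0.49 ± 0.07 (0.0012), but did not pass with the donor as a random block (adjusted p = 0.39). Of the 31 lists, 4 held a gene that passed, with the same counts when adjusted over the list alone: 2 of 7 oligodendrocyte markers, 1 of 27 lysosome genes, 1 of 16 alternative activation genes and 1 of 8 dendritic cell markers. Camera placed the oligodendrocyte list higher (adjusted p = 0.00037) and cholesterol synthesis lower (0.0088, median −0.02), but adjusted p = 0.22 and 0.65 with an estimated correlation. ABCA1 and ABCG1, the transporters that export cholesterol, had changes of −0.07 ± 0.06 and −0.02 ± 0.10, and RXRA and RXRB −0.07 ± 0.06 and −0.05 ± 0.05 (adjusted p of at least 0.86). Without the donor block 4 genes passed, and of the genes named here only MBP, MOBP and GGT5 were among them. Leaving out healthy replicate 2 left 32 genes and MS replicate 1 left 33.

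**Figure D2:**
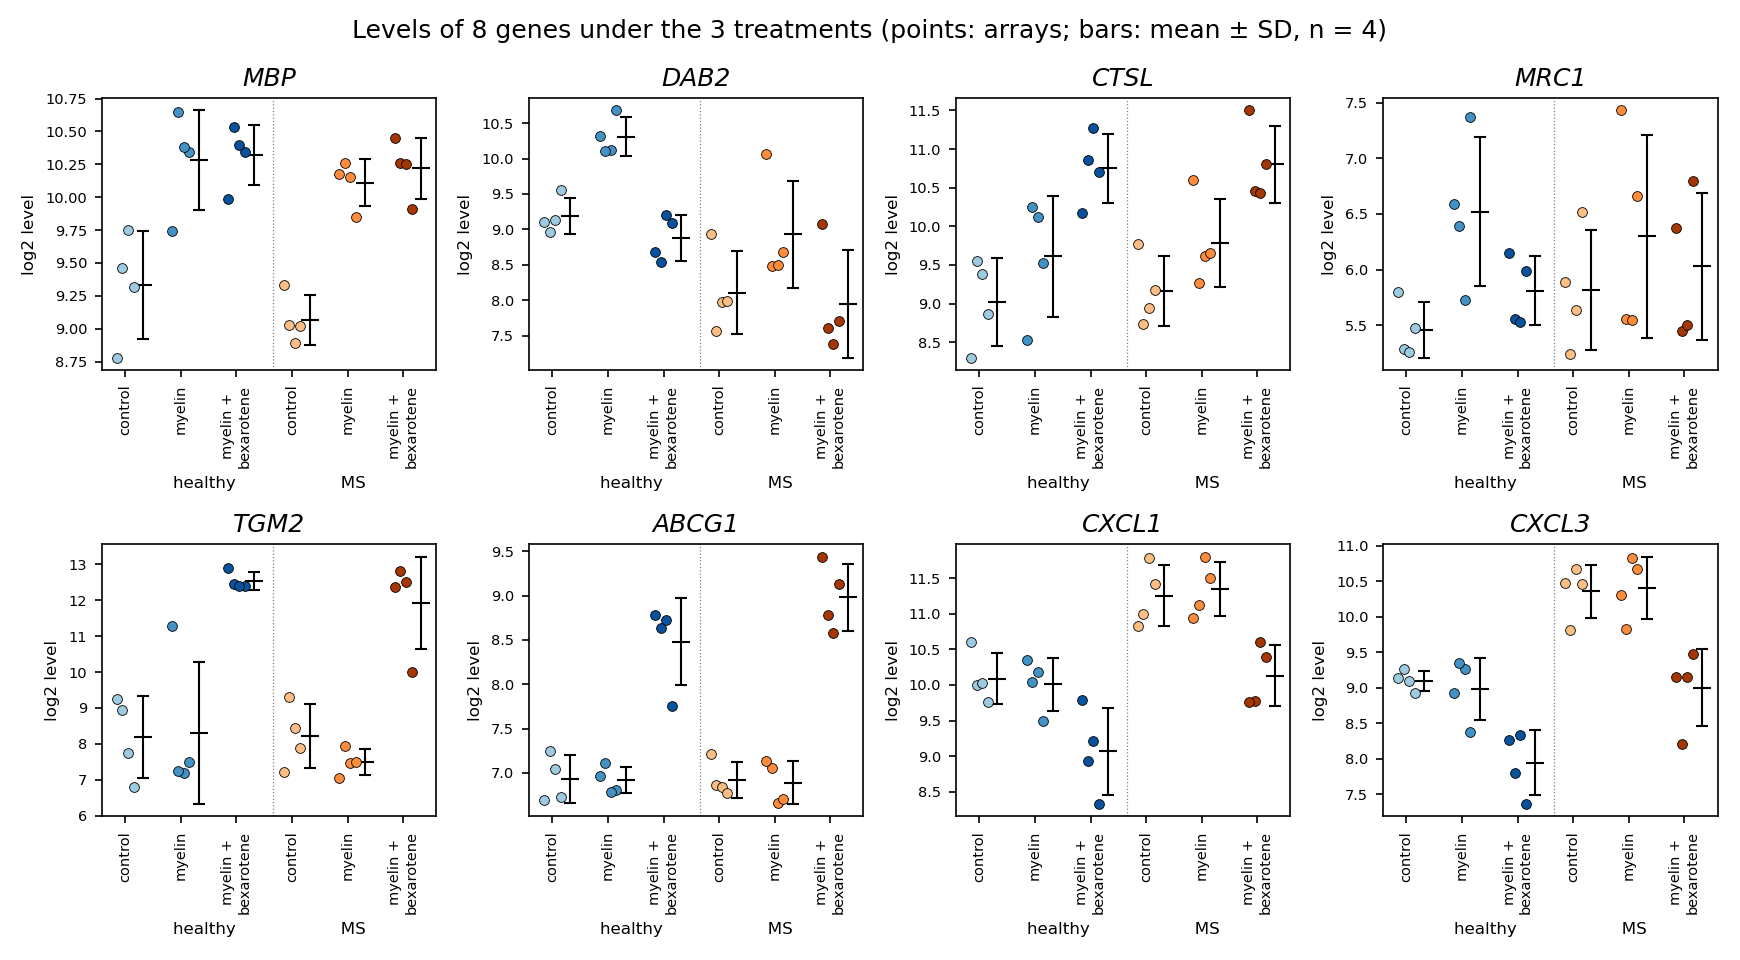
Log2 levels of MBP, DAB2, CTSL, MRC1, TGM2, ABCG1, CXCL1 and CXCL3 on each array by group, with the mean ± SD of 4 arrays. MBP rose with myelin (1.00 on average) and stayed there with bexarotene (0.07), while TGM2 and ABCG1 rose with bexarotene.

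Each diagnosis responded to myelin with a short list. In healthy donors 27 genes rose and 0 fell (limma, 510 genes at an unadjusted p under 0.05), among them DAB2 (1.12 ± 0.11), GGT5 (0.99 ± 0.11) and MBP (0.95 ± 0.09). In MS donors 20 rose and 2 fell: MBP rose by 1.04 ± 0.09, EMP1 by 0.83 ± 0.13, DAB2 by 0.82 ± 0.11, and IL19, a cytokine of the interleukin-10 family, by 1.28 ± 0.21 (adjusted p = 0.012). The falls were TEKT5 (−0.32 ± 0.06) and FLJ42627 (−0.26 ± 0.05). Of the genes raised, 18 were shared, against 0.0413 for independent lists. Across genes, which are not independent, the effects had r = 0.31 and the same sign in 54.5%. In the test of the difference between diagnoses 0 genes passed with limma and 474 had an unadjusted p under 0.05. The count was 0 under each alternative too, with 151 (no donor block) to 913 (array weights) at an unadjusted p under 0.05. The 5 of smallest p, TEKT5 (−0.44 ± 0.08), GEMIN4 (−0.51 ± 0.11), CRYBA4 (−0.38 ± 0.08), MAF (−0.44 ± 0.11) and TEX29 (−0.31 ± 0.08), did not pass (adjusted p of at least 0.67). The metallothionein list was higher in that difference by camera (0.025), but not with an estimated correlation (adjusted p = 0.96). ABCA1, ABCG1, RXRA and RXRB did not pass in either diagnosis, with changes of −0.01 each in healthy donors and −0.13, −0.03, −0.13 and −0.08 in MS donors. Their differences between diagnoses were −0.11, −0.02, −0.12 and −0.07.

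These short lists depended on single donors and on the block. The fit without the donor block gave 0 genes in healthy donors (limma, 137 at an unadjusted p under 0.05) and 0 in MS donors (233), and the random block gave 16 and 7. In MS donors DAB2 (adjusted p = 0.11), EMP1 (0.11), TEKT5 (0.067) and FLJ42627 (0.75) did not pass with the random block, nor EMP1 (0.065), TEKT5 (0.11) and FLJ42627 (0.14) in a fit of only the 12 arrays of that diagnosis. With trend and robust eBayes IL19 (0.12) and TEKT5 (0.068) did not pass, nor FLJ42627 without the filter (0.059). In healthy donors 16 genes passed without healthy replicate 2 and 16 without healthy replicate 3. In MS donors 8 passed without MS replicate 1, 8 without MS replicate 2 and 14 without MS replicate 3. IL19 no longer passed without any of these 3 (adjusted p = 0.26, 0.19 and 0.12), nor did TEKT5 (0.34, 0.12 and 0.27) or FLJ42627 (0.34, 0.18 and 0.17). TEKT5 also did not pass without MS replicate 4 (0.061) or healthy replicate 2 (0.059), nor FLJ42627 without MS replicate 4 (0.24), healthy replicate 1 (0.053) or healthy replicate 3 (0.073).

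Bexarotene raised retinoic acid and LXR target genes in monocytes that had myelin. TGM2, a transglutaminase induced by retinoic acid, rose by 4.32 ± 0.37, which is 20-fold (adjusted p = 2.1e-08), and the prostaglandin E synthase PTGES by 3.44 ± 0.17 (2.1e-11). ABCG1 rose by 1.82 ± 0.10 (4.7e-11) and ABCA1 by 1.23 ± 0.06 (1.1e-11). The interleukin-10 family cytokines IL19 and IL24 fell by 1.83 ± 0.15 and 1.73 ± 0.15, and the neutrophil chemokines CXCL1 and CXCL3 fell by 1.08 ± 0.06 and 1.23 ± 0.09, all in 8 of 8 donors. Over all donors 1411 genes rose and 1459 fell, of which 93 rose and 49 fell by more than 2-fold, and 4164 had an unadjusted p under 0.05.

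Further large increases, each in 8 of 8 donors, were the Src-like adaptor SLA (2.96 ± 0.18), the retinal reductase DHRS3 (2.80 ± 0.17), the growth factor HBEGF (2.78 ± 0.19), the pyruvate dehydrogenase kinase PDK4 (2.58 ± 0.16), the interleukin-2 receptor chain IL2RA (2.45 ± 0.18) and the corepressor NRIP1 (2.32 ± 0.11). Further large falls were the potassium channel KCNJ15 (−2.05 ± 0.12), the vanin pseudogene VNN3P (−1.79 ± 0.07), LHFPL2 (−1.76 ± 0.10), RGL1 (−1.71 ± 0.07), the transcriptional repressor PRDM1 (−1.69 ± 0.06) and NFXL1 (−1.63 ± 0.10). The fit without the donor block called 566 genes higher and 350 lower.

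Targets of LXR and of the retinoic acid receptors rose as lists. Of 13 LXR targets 10 rose and 1 fell, including the lipid regulator SREBF1 (0.61 ± 0.04) and SMPDL3A (0.82 ± 0.07), and of 11 retinoic acid targets 7 rose and 1 fell, including ASB2 (2.11 ± 0.09), thrombomodulin THBD (1.82 ± 0.13) and HIC1 (1.49 ± 0.05), with the same counts adjusted over the list alone. Camera gave adjusted p = 1.4e-08 and 6.9e-06 for these, and adjusted p = 0.0021 and 0.012 with an estimated correlation. Of 14 PPAR targets 7 rose and 1 fell (9 and 1 adjusted over the list alone), among them the lipase MGLL (0.98 ± 0.06) and the lipid droplet protein PLIN2 (0.69 ± 0.06). Its camera call (9e-05) was lost with an estimated correlation (adjusted p = 0.14). Of 12 genes of the RXR family and its partners 5 rose and 1 fell (5 and 2 adjusted over the list alone): RARG rose by 0.77 ± 0.07 and PPARG by 0.57 ± 0.07, while RXRA (−0.06 ± 0.06) and RXRB (−0.03 ± 0.05) did not pass (camera 0.18). PPARG did not pass in the fit without the donor block (adjusted p = 0.23).

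Inflammatory lists held more falls than increases. Of 29 NF-kappaB cytokines and chemokines 3 rose and 13 fell (3 and 14 adjusted over the list alone). CCL5 fell by 0.62 ± 0.04, and IL6, a gene chosen after its values were seen, fell by 1.35 ± 0.13 (adjusted p = 1.1e-07), whereas the chemokine CCL20 rose by 0.94 ± 0.09 (1e-07). Of 17 immediate early genes 2 rose and 8 fell (2 and 10 adjusted over the list alone), with KLF6 at −0.60 ± 0.05 and JUN at 0.73 ± 0.14. Camera placed these 2 lists lower (0.0017 and 0.026), but adjusted p = 0.54 and 0.62 with an estimated correlation. Of 25 interferon response genes 2 rose and 6 fell, with CXCL10 at −0.81 ± 0.07, GBP5 at −0.62 ± 0.06 and OASL at 0.71 ± 0.05 (camera 0.31). In the fit without the donor block IL6 (adjusted p = 0.074) and JUN (0.12) did not pass.

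Lysosome and phagocytosis lists moved in both directions. Of 27 lysosome genes 10 rose and 2 fell: CTSL rose by 1.08 ± 0.08 and the glucuronidase GUSB by 0.54 ± 0.06, and the proton pump subunit ATP6V1H fell by 0.47 ± 0.05 (camera 0.14). Of 25 phagocytic and scavenger receptors 5 rose and 4 fell, with CD93 at 0.70 ± 0.07 and the scavenger receptor MSR1 at −0.62 ± 0.07 (camera 0.92). Of 23 genes for the actin of the phagocytic cup 4 rose and 2 fell (5 and 3 adjusted over the list alone), with VAV1 at 0.44 ± 0.06 in 7 of 8 donors (camera 0.92 upward, median −0.01 and mean 0.01). Of 16 alternative activation genes 1 rose and 3 fell, with the decoy receptor IL1R2 at −0.73 ± 0.06 and MRC1 at −0.49 ± 0.15 (adjusted p = 0.019; camera 0.62). Of 14 monocyte markers 4 fell and no other passed, with CD300E at −1.03 ± 0.07 and CX3CR1 at −0.59 ± 0.11. That list's camera call (0.026) was lost with an estimated correlation (adjusted p = 0.45). With the block left out MSR1 (adjusted p = 0.18), MRC1 (0.43), IL1R2 (0.061), ATP6V1H (0.079) and CX3CR1 (0.41) did not pass, and MRC1 missed the threshold without healthy replicate 2 or healthy replicate 4 (0.059 each) or with trend and robust eBayes (0.056).

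Bexarotene raised and lowered many of the same genes in both diagnoses. In healthy donors 993 genes rose and 932 fell, and in MS donors 831 rose and 850 fell. TGM2 rose by 4.22 ± 0.52 and 4.43 ± 0.52 in healthy and MS donors, PTGES by 3.52 ± 0.24 and 3.36 ± 0.24, ABCA1 by 1.18 ± 0.08 and 1.28 ± 0.08, and ABCG1 by 1.56 ± 0.14 and 2.09 ± 0.14. RXRA (−0.06 ± 0.08 in each) and RXRB (−0.09 ± 0.07 and 0.03 ± 0.07) did not pass. The mean changes of TGM2 were lowered by single donors. With myelin alone TGM2 stood at 11.28 in healthy replicate 1, against 7.2 to 7.51 in the other healthy donors. With bexarotene it stood at 10.01 in MS replicate 4, against 12.36 to 12.8 in the other MS donors. Among the largest falls were KCNJ15 (−2.22 ± 0.17) and the reductase STEAP4 (−1.75 ± 0.08) in healthy donors and IL19 (−2.14 ± 0.21) and VNN3P (−1.98 ± 0.10) in MS donors. TNFSF18 fell in MS donors to a mean of 4.45 ± 0.33 (SD, n = 4), under the filter values of 5.8 to 5.87 of the arrays, so the size of its fall may be limited by the floor. The same holds for the sizes of change of IL24, JAKMIP2, MOBP, MRC1 and TEKT5, which also had group means under these values. The lists shared 611 genes raised and 544 lowered, against 63.1 and 60.6 for independent lists. Across genes, which are not independent, the effects had r = 0.85 and the same sign in 65.9%. With no donor block 313 genes rose and 117 fell in healthy donors, and 237 rose and 106 fell in MS donors, so that 72.8% and 69.1% of calls were higher against 51.6% and 49.4%.

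**Figure D3:**
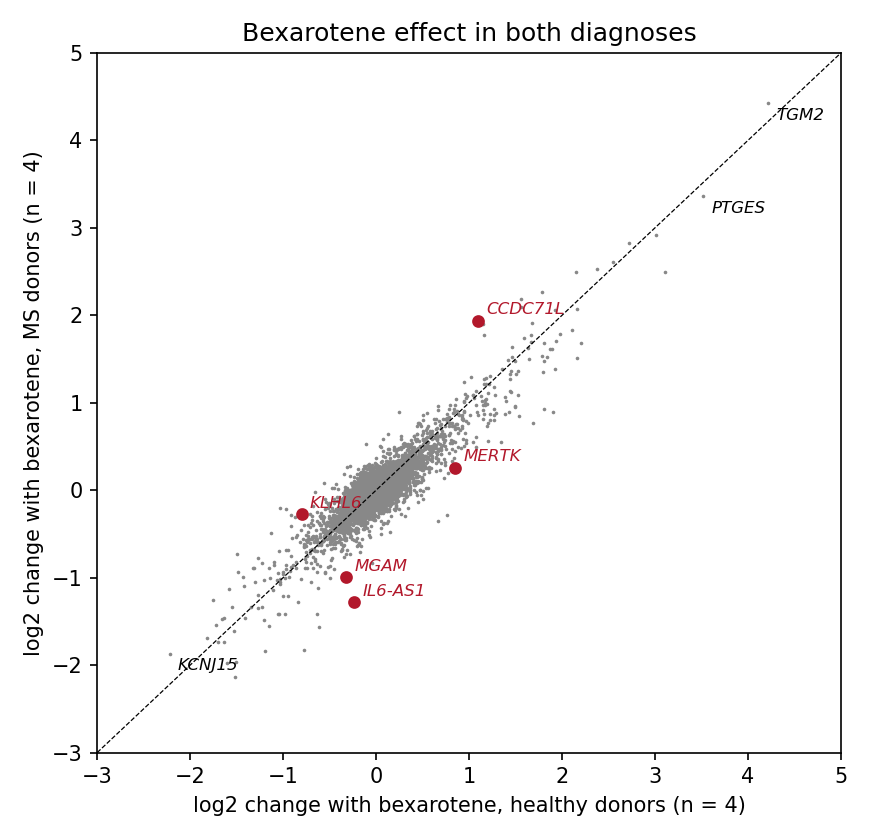
Log2 change with bexarotene of each gene tested in healthy donors (horizontal) and MS donors (vertical), with a line of equal change. The 5 genes that passed the test of a difference between diagnoses, where 2 of 35 splits of the donors gave as many, are in red, and r across genes was 0.85.

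In the test of the difference between diagnoses 5 genes passed, and as 2 of 35 splits of the donors gave as many, chance cannot be excluded. CCDC71L rose by 1.10 ± 0.08 in healthy and 1.94 ± 0.08 in MS donors, a difference of 0.83 ± 0.12 (adjusted p = 0.0096). KLHL6 fell by 0.80 ± 0.05 and 0.27 ± 0.05 (difference 0.53 ± 0.08, 0.011). MERTK, a receptor for dying cells, rose by 0.85 ± 0.07 and 0.26 ± 0.07 (difference −0.59 ± 0.10, 0.034), and the glucosidase MGAM fell by 0.32 ± 0.08 and 0.99 ± 0.08 (difference −0.67 ± 0.11, 0.034). IL6-AS1, a non-coding transcript at the IL6 locus, had changes of −0.24 ± 0.13 (adjusted p = 0.25) and −1.28 ± 0.13 (difference −1.04 ± 0.18, 0.034), but its mean in healthy donors lay under the filter values before bexarotene (5.39), so a fall there may be hidden by the floor. Differences for ABCA1 (0.11), ABCG1 (0.54 ± 0.20, adjusted p = 0.51), RXRA (0.00) and RXRB (0.13) did not pass. The count was 0 without the donor block (limma, 240 at an unadjusted p under 0.05) and 1 with a random block, where KLHL6 (adjusted p = 0.36), IL6-AS1 (0.32), MGAM (0.73) and MERTK (0.43) did not pass. IL6-AS1 missed the threshold after quantile normalization (0.083) and MERTK with array weights (0.053). The count was 0 without MS replicate 3 (990 at an unadjusted p under 0.05), 1 without healthy replicate 1 or healthy replicate 2, 2 without healthy replicate 3 or MS replicate 4, and 8 without healthy replicate 4 or MS replicate 1. Of the donors left out in turn, only MS replicate 3 ended the call of CCDC71L (0.055). Without healthy replicate 1, healthy replicate 2 or MS replicate 3, KLHL6 (0.066, 0.1 and 0.07), IL6-AS1 (0.16, 0.1 and 0.066), MGAM (0.16, 0.1 and 0.057) and MERTK (0.15, 0.1 and 0.055) missed it. So did IL6-AS1, MGAM and MERTK without healthy replicate 3 (0.076, 0.088 and 0.088) or MS replicate 4 (0.16 each), IL6-AS1 and MGAM without healthy replicate 4 (0.1 and 0.084), MGAM without MS replicate 2 (0.054) and MERTK without MS replicate 1 (0.1).

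Genes raised by myelin were often lowered by bexarotene. Of the 50 genes that rose with myelin, 27 fell and 11 rose when bexarotene was added, against 5.58 and 5.39 for independent lists. DAB2 and EMP1 were among those that fell, whereas MBP and MOBP changed by 0.07 ± 0.06 and 0.07 ± 0.07 (adjusted p = 0.49 and 0.55). The comparisons share the myelin arrays, so lists from opposite diagnoses, whose effects share none, were compared too. Of 27 genes raised by myelin in healthy donors 13 fell with bexarotene in MS donors and 4 rose (1.75 and 1.72 for independent lists), and of 20 raised in MS donors 11 fell and 3 rose with bexarotene in healthy donors (1.42 and 1.52). Random lists matched on level and variability held more falls than independent lists, with medians of 6 and 5, and 15 over all donors. Across all genes, which are not independent, r between the effects was −0.0036 in the same donors, where simulated unchanged groups gave −0.50 (−0.52 to −0.46 in 100 simulations). The covariance was −5.79e-05 against a simulated −0.00159, a difference of 0.00154. Between opposite diagnoses r was 0.12 and −0.0022; the first was −0.038 without healthy replicate 1, and the second was −0.042 without MS replicate 1 and 0.025 without MS replicate 2.

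Against control, myelin with bexarotene gave 1987 genes higher and 1576 lower. Quantile normalization again gave 1674 higher and 2012 lower, so that 45.4% of calls were higher against 55.8%. TGM2 (4.02 ± 0.37), PTGES (3.35 ± 0.17), HBEGF (3.33 ± 0.19) and SLA (3.00 ± 0.18) rose most, and LHFPL2 (−1.81 ± 0.10), KCNJ15 (−1.78 ± 0.12) and NFXL1 (−1.76 ± 0.10) were among the largest falls. ABCA1 rose by 1.16 ± 0.06 and ABCG1 by 1.81 ± 0.10. LXR targets (9 of 13 rose, 1 fell), retinoic acid targets (7 of 11, 1 fell), PPAR targets (10 of 14, 1 fell), NF-kappaB cytokines (6 of 29 rose, 14 fell) and oxidative phosphorylation (9 of 20 rose) passed with camera (adjusted p = 6.1e-06, 6.1e-06, 0.00019, 0.0028 and 0.022). With an estimated correlation the first pair passed (adjusted p = 0.011 and 0.012) and the rest did not (adjusted p = 0.17, 0.58 and 0.58). Adjusted over the list alone, the counts were 9 and 1, 8 and 1, 10 and 1, 7 and 18, and 9. RXRA (−0.13 ± 0.06, adjusted p = 0.095) and RXRB (−0.08 ± 0.05, 0.29) did not pass, although RXRA passed without healthy replicate 4 (0.045) or MS replicate 1 (0.025), and with centring (0.047), quantile normalization (0.042) or array weights (0.029). With no donor block 689 genes were higher and 423 lower.

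**Figure D4:**
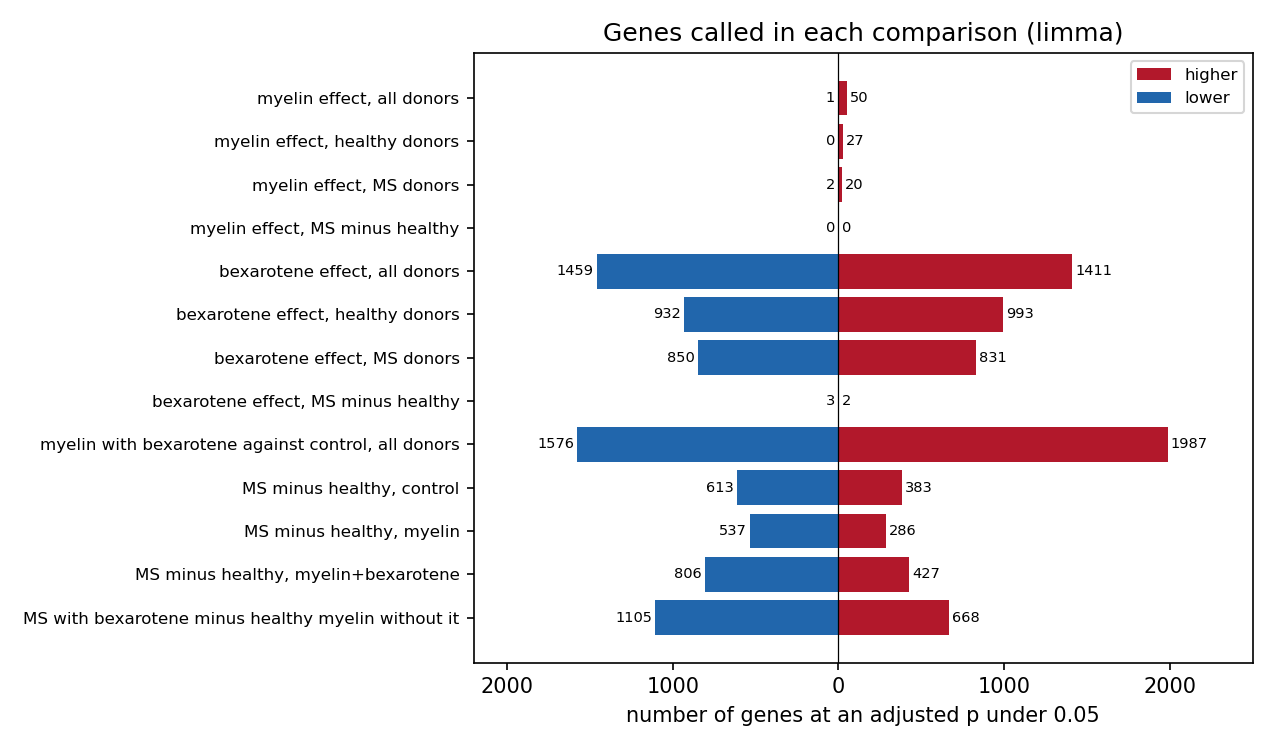
Number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each comparison, from limma over 13081 genes. Bexarotene called 1411 and 1459 genes over all donors, and myelin 50 and 1.

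Untreated monocytes of MS donors had higher inflammatory transcripts than those of healthy donors. The cytokine IL6 was higher by 2.22 ± 0.47 (adjusted p = 0.0064), F3, which encodes tissue factor, by 2.05 ± 0.31 (0.00065), the lipase gene LIPN by 2.19 ± 0.29 (0.00023) and the transcription factor E2F7 by 1.95 ± 0.28 (0.00039). Lower were CD180, a Toll-like receptor homologue (−1.93 ± 0.34, 0.0017), JAKMIP2 (−1.69 ± 0.26, 0.00065), the chemokine receptor CXCR4 (−1.56 ± 0.19, 9.7e-05) and the lysosomal fucosidase FUCA1 (−1.53 ± 0.32, 0.0064). Of 29 NF-kappaB cytokines and chemokines 16 were higher (22 adjusted over the list alone). Examples chosen after their values were seen were CCL20 (1.75 ± 0.21), TNF (1.49 ± 0.30), CXCL3 (1.26 ± 0.24) and CXCL1 (1.16 ± 0.22). The list passed with camera (adjusted p = 3.1e-17) and had adjusted p = 0.039 with an estimated correlation. The SE here, and in the MS comparisons below, rests on a donor correlation shared by all genes. It can therefore understate the spread between donors. Over the donors of healthy and MS controls (n = 4 each), the SDs were 0.76 and 0.99 for IL6 and 0.89 and 0.36 for TNF. They were 0.17 and 0.9 for CD180, 0.42 and 0.32 for CCL20, 0.14 and 0.37 for CXCL3, and 0.36 and 0.43 for CXCL1.

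In control arrays 383 genes were higher and 613 lower in MS donors (n = 4 against 4), of which 60 and 22 by more than 2-fold, and 3091 had an unadjusted p under 0.05. Higher lists were metallothioneins (3 of 7, or 6 adjusted over the list alone), immediate early genes (6 of 17, or 9) and antigen presentation (2 of 17, or 4), with MT2A at 0.73 ± 0.14 and EGR1 at 1.17 ± 0.25, both chosen after their values were seen. Their camera calls (3.9e-05, 8.1e-05 and 0.0017) were lost with an estimated correlation (adjusted p = 0.39 for each). Of 27 lysosome genes 3 were lower, among them the lysosomal lipase LIPA (−0.61 ± 0.12), also chosen after its values were seen. The 14 monocyte markers had a median difference of −0.01, and medians of the lists of T, B, NK and dendritic cells, platelets, neutrophils and erythroid cells lay between −0.02 and 0.14. ABCA1 (0.42 ± 0.17, adjusted p = 0.12), ABCG1 (−0.01 ± 0.22), RXRA (−0.29 ± 0.13, 0.18) and RXRB (−0.19 ± 0.13, 0.37) did not pass, and ABCA1 passed without healthy replicate 2 (0.57, adjusted p = 0.047). In a simulated set of arrays for this comparison 17.1% of the calls were of unchanged genes, above the 5% the threshold stands for. A fit on only the 8 control arrays called 64 genes higher and 62 lower, and IL6 (adjusted p = 0.067), TNF (0.087), CD180 (0.053), FUCA1 (0.086), CXCL1 (0.054), EGR1 (0.094), MT2A (0.08) and LIPA (0.064) did not pass there. Without the donor block TNF (0.052), EGR1 (0.052) and FUCA1 (0.055) missed the threshold. The count was 415 without MS replicate 4, 552 without MS replicate 2, 582 without MS replicate 3, 597 without healthy replicate 1 and 641 without healthy replicate 2.

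**Figure D5:**
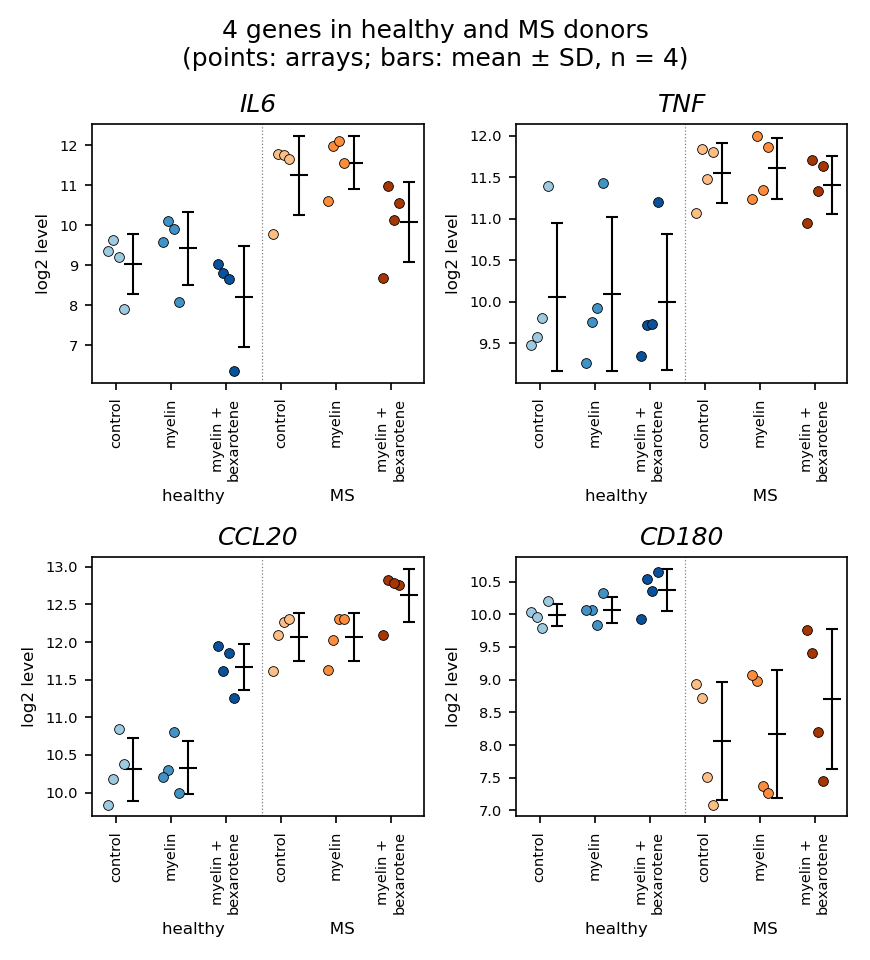
Log2 levels of IL6, TNF, CCL20 and CD180 on each array by group, with the mean ± SD of 4 arrays. IL6, TNF and CCL20 had higher means and CD180 a lower mean in MS donors under each of the 3 treatments.

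With myelin, 286 genes were higher and 537 lower in MS donors. LIPN (2.33 ± 0.29, adjusted p = 0.00012), IL6 (2.15 ± 0.47, 0.0082) and F3 (2.11 ± 0.31, 0.00064) were higher, and CD180 (−1.90 ± 0.34, 0.0022), CXCR4 (−1.51 ± 0.19, 0.00012) and the uptake adaptor DAB2 (−1.38 ± 0.27, 0.0044) were lower. NF-kappaB cytokines were higher for 17 of 29 (23 adjusted over the list alone), including CCL20 (1.74 ± 0.21) and TNF (1.52 ± 0.30), both chosen after their values were seen. The camera call of that list (7e-23) had adjusted p = 0.011 with an estimated correlation. Metallothioneins (5 of 7, or 7 adjusted over the list alone), immediate early genes (4 of 17, or 8), antigen presentation (2 of 17, or 4), interferon response (1 of 25, or 1) and extracellular matrix (2 of 12, or 2) had camera p of 5.6e-09, 4.4e-06, 0.00074, 0.037 and 0.046. None of these passed with an estimated correlation (adjusted p = 0.089, 0.37, 0.44, 0.91 and 0.52). RXRA (−0.41 ± 0.13, adjusted p = 0.064), RXRB (−0.26 ± 0.13, 0.26), ABCA1 (0.31 ± 0.17, 0.31) and ABCG1 (−0.03 ± 0.22, 0.97) did not pass, although RXRA passed without MS replicate 2 (−0.52, 0.034) and with array weights (0.023). Of the control calls 236 were also higher and 390 also lower with myelin (8.37 and 25.2 for independent lists), in other arrays of the same donors, who bring the same differences to both. The split moved from 34.8% higher to 48.6% after centring (353 and 373) and 46.1% after quantile normalization (350 and 409). With no donor block 494 genes passed, and not IL6 (0.055) or TNF (0.056). The 8 myelin arrays alone gave 12 higher and 6 lower, where IL6 (0.086), TNF (0.13), F3 (0.063), CD180 (0.086), CXCR4 (0.058) and DAB2 (0.1) did not pass. The count was 335 without MS replicate 4, 454 without MS replicate 3 and 536 without healthy replicate 2.

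With myelin and bexarotene, 427 genes were higher and 806 lower in MS donors. LIPN (2.04 ± 0.29), F3 (1.94 ± 0.31), E2F7 (1.89 ± 0.28), IL6 (1.89 ± 0.47) and TREML4 (1.77 ± 0.35) were higher, and SLC45A4 (−1.86 ± 0.26), CD180 (−1.66 ± 0.34) and the transmembrane glycoprotein GPNMB (−1.44 ± 0.30) were lower (adjusted p of at most 0.013). NF-kappaB cytokines were higher for 16 of 29 (20 adjusted over the list alone), with TNF (1.41 ± 0.30) and CCL20 (0.95 ± 0.21), and metallothioneins for 6 of 7 (7 adjusted over the list alone), with MT2A (0.81 ± 0.14), these 3 genes chosen after their values were seen. Antigen presentation (4 of 17 higher, or 5 adjusted over the list alone) and immediate early genes (3 of 17, or 5) were higher, and lysosome genes (4 of 27, or 7) lower. These 5 lists passed with camera (8.1e-14, 9.9e-08, 0.0057, 0.007 and 0.038), and none with an estimated correlation (adjusted p = 0.095, 0.15, 0.54, 0.73 and 0.54). RXRA (−0.41 ± 0.13, adjusted p = 0.051), RXRB (−0.13 ± 0.13, 0.55), ABCA1 (0.42 ± 0.17, 0.12) and ABCG1 (0.51 ± 0.22, 0.15) did not pass. RXRA passed without healthy replicate 1 (0.048), MS replicate 1 (0.022) or MS replicate 2 (0.031), without the filter (0.048), with array weights (0.02) and, just under the threshold, with trend and robust eBayes (0.05). The split moved from 34.6% higher to 45.2% after centring (531 and 644) and 45.0% after quantile normalization (515 and 629). The 8 arrays alone gave 64 higher and 92 lower, where IL6 (0.16), TNF (0.083), CCL20 (0.054), CD180 (0.093), GPNMB (0.083) and TREML4 (0.076) did not pass. All probe sets gave 1950 calls, and the count was 780 without MS replicate 3 and 472 without MS replicate 4, while IL6 missed the threshold without MS replicate 2 (0.063), MS replicate 4 (0.073) or the donor block (0.065), and TNF without the block (0.054).

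MS monocytes with bexarotene were set against healthy monocytes with myelin alone, and 668 genes were higher and 1105 lower. The split moved from 37.7% higher to 47.1% after centring (783 and 881) and 44.9% after quantile normalization (790 and 968). Bexarotene targets led this difference, with PTGES (3.55 ± 0.39), TGM2 (3.61 ± 0.81), SLA (2.97 ± 0.38), IL2RA (2.89 ± 0.46), CCL23 (2.57 ± 0.53), ABCG1 (2.06 ± 0.22) and ABCA1 (1.59 ± 0.17) higher. KCNJ15 (−2.43 ± 0.33), DAB2 (−2.36 ± 0.27), NFXL1 (−2.28 ± 0.35) and LHFPL2 (−2.25 ± 0.27) were lower. LXR targets (7 of 13 higher, or 8 adjusted over the list alone) and retinoic acid targets (7 of 11, or 8) passed with both camera settings (adjusted p = 0.0014 and 0.0016 with an estimated correlation). NF-kappaB cytokines (9 of 29, or 11), metallothioneins (7 of 7, or 7), PPAR targets (4 of 14, or 7) and antigen presentation (3 of 17, or 4 higher and 1 lower) passed with the preset one (1.4e-07, 1.4e-07, 0.023 and 0.0028) and not with an estimated correlation (adjusted p = 0.18, 0.11, 0.26 and 0.43). RXRA was lower (−0.47 ± 0.13, adjusted p = 0.018), but not without healthy replicate 2 (0.077), healthy replicate 4 (0.057), MS replicate 3 (0.081) or MS replicate 4 (0.12), and RXRB did not pass (−0.23 ± 0.13, 0.27). The 8 arrays alone gave 653 calls, where TGM2 (0.069), CCL23 (0.079) and RXRA (0.13) did not pass.

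Along the axis from healthy to MS control arrays, bexarotene moved MS monocytes by −7.6 ± 7.9% of the difference (SD, n = 4), towards the healthy side in 3 of 4 donors (exact sign-flip permutation p = 0.25, two-sided). Healthy monocytes moved by −5.1 ± 7.8% (SD, n = 4, exact p = 0.25), negative in 3 of 4 donors. The difference between the shifts was −2.5% (exact permutation p = 0.686). Sign flips of 4 donors cannot give a p under about 0.13. Over the 500 genes of largest difference the shift was −14.2 ± 4.5% in MS donors, negative in 4 of 4. In healthy donors it was −3.3 ± 8.8%, negative in 3 of 4 (exact permutation p = 0.0857 for the difference). Of the 383 genes higher in MS controls, 97 fell with bexarotene in MS donors and 38 rose, against 24.9 and 24.3 for independent lists. Of the 613 lower ones 47 rose and 70 fell, against 38.9 and 39.8. Random lists matched on level and variability were not drawn for these genes. For the genes raised by myelin such lists held more falls than independent lists did.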

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

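The tests of transcripts and total RNA brought in with the isolate, of the shared myelin arrays, and both tests of the share of monocytes were chosen after the results they concern had been seen; the splits of samples, the matched random lists and the search for batch labels were chosen before.

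MBP and MOBP rose with the myelin isolate, a preparation of a tissue that makes both transcripts. A candidate explanation is that transcripts came in with the isolate. Neither gene changed by more than 1.13 standard errors when bexarotene was added, while 38 of the 48 other genes raised by myelin did change. This cannot decide it, since most genes tested did not pass with bexarotene either (2870 of 13081 passed). The 48 genes were also picked on myelin arrays that the bexarotene effect shares. MBP had log2 means of 9.33 in healthy and 9.07 in MS controls, above the filter values before any isolate was given. MBP rose by 0.95 in healthy and 1.04 in MS donors, with an SD of 0.22 over donors. Total RNA of oligodendrocytes would bring their other transcripts too, and the other 13 members of that list on the array had a median change of 0.04 (SD 0.04) and a largest of 0.08, without the filter. It cannot be told apart all the same, since 8 of the 13 lay near the floor and the amount of each transcript in the isolate was not measured. A response of the monocytes, which myelin treatment as a group of the design could give, stays open, as the isolate was not measured alone.

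Of the genes raised by myelin, 27 of 50 fell with bexarotene. The shared myelin arrays as the whole cause are excluded by the exchange of diagnoses, in which 13 of 27 genes raised in healthy donors fell in MS donors and 11 of 20 the other way, with no array in common. A general lowering of genes of such level and variability is excluded as the whole cause too: of 10000 random lists matched on both, a share of 0.004 and 0.005 had as many, with medians of 6 and 5 and highest counts of 16 each. Over all donors the share was 3e-04 with a median of 15. That share cannot count against a general lowering, on which only the exchanges of diagnosis bear. The 50 genes over all donors were picked on myelin arrays that the bexarotene effect shares, which favours falls, and the random lists were not picked so. A hypothesis that stays open is that bexarotene opposes part of the myelin response. With no samples given bexarotene alone, bexarotene may as well lower these genes in the absence of myelin. Any such opposition was limited to some genes: 11 of the 50 rose further with bexarotene. Across all genes r between opposite diagnoses was 0.12 and −0.0022, so no opposite run showed as a whole. This r cannot decide it, since the myelin effect had r of only 0.31 between diagnoses, which keeps its r with another effect small.

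MS and healthy donors differed in 996 genes in control arrays. The 14 monocyte markers had a median of −0.01 (SD 0.24), so as a list they did not fall as far as the genes lower in MS (median −0.47). This cannot exclude a lower share of monocytes in the MS samples, since those genes were picked for being lower in the same arrays. The samples were CD14+ monocytes, a selection that would remove other blood cells, but a small difference in their share cannot be told apart from the rest, as the medians of their 7 marker lists lay between −0.02 and 0.14 with standard errors of up to 0.21. Handling or culture that differed between the sets of donors may be the cause as well as the disease, since the labels gave 0 batch labels and each diagnosis is one set of donors. Disease and other differences between donors stay open and were not tested.

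Other splits of the samples were fitted in the same way. For the myelin effect over all donors, 1 of 100 exchanges of a donor's arrays gave as many calls, the real one, with 51 genes against 15 for the highest other, and chance can be excluded. The same holds for bexarotene (1 of 100, 2870 against 2096) and for myelin with bexarotene against control (1 of 100, 3563 against 2556). These highest others exchanged 1 donor of the 8 and so kept most of the effect; with 2 or more exchanged the highest counts were 1, 91 and 124. Within a diagnosis the 8 exchanges are too few for a share under 0.05: the counts were 27 against 1 and 22 against 0 for myelin and 1925 against 4 and 1681 against 13 for bexarotene, the real one being the 1 largest of 8 each time. For MS against healthy donors chance is unlikely in control (1 of 35 splits, 996 against 64), myelin (1 of 35, 823 against 52) and myelin with bexarotene (1 of 35, 1233 against 116). A share of 1 of 35 is the smallest these splits can give. The comparisons rest on the same 8 donors, so they are not separate results. For the difference of the bexarotene effects chance cannot be excluded, as 2 of 35 splits gave as many (5 against 5), and for that of the myelin effects 35 of 35 gave 0 genes. MS with bexarotene against healthy myelin gave 1773 genes, with 2 of 70 splits as large. The other was the mirror, healthy with bexarotene against MS myelin, at 2180, and the highest mixed split had 1131. Mirrored splits were counted apart here because the contrast is not symmetric, a departure from the 35 splits first written down. Each split sets arrays with bexarotene against arrays without it, and the others had a median of 503.

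In the test of a difference in the bexarotene effect between diagnoses, where chance cannot be excluded, 5 genes passed: CCDC71L by 0.83, KLHL6 by 0.53, MERTK by −0.59, MGAM by −0.67 and IL6-AS1 by −1.04, MS minus healthy. In 268 checks of groups of values some groups came up more than once, so fewer than 268 different groups were searched. Of these, 25 held a value far from the others, where chance alone gives about 1 in 20. The gap of that value to its nearest neighbour, as a share of the group's range, is given for each and lay above Dixon's critical value for 4 or 8 values. Among the 8 donors' bexarotene changes it was 0.672 for IL19, 0.632 for VNN3P, 0.627 for NFXL1, 0.575 for GUSB, 0.537 for SQLE, 0.663 for CX3CR1 and 0.648 for VAV1. In healthy controls it was 0.862 for JAKMIP2 and 0.835 for TNF, and in MS controls 0.934 for IL6. With myelin it was 0.925 for TGM2 and 0.974 for PTGES in healthy donors, and 0.875 for DAB2, 0.936 for RXRA and 0.897 for the second principal component in MS donors. With bexarotene it was 0.854 for IL6 and 0.861 for ABCG1 in healthy donors, and 0.898 for CCL20, 0.842 for TGM2, 0.88 for TNFSF18, whose mean of 4.45 lay under the filter values, and 0.902 for CCL23 in MS donors. Among changes within a diagnosis it was 0.906 for ABCA1 with myelin in healthy donors, 0.864 for EMP1 with myelin in MS donors, and 0.919 and 0.844 for TGM2 with bexarotene in healthy and MS donors.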

How the results depend on the processing

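No alternative here was chosen after the data were examined. Changes of the genes named, under each alternative, kept direction and side of the threshold in 3162 cases, lost the threshold in 175, gained it in 14 and changed sign in 35, the last only for genes that had not passed; the cause was not tested.

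The replicate number names the donor, so the fit with the donor block takes out differences between donors. Without the block the counts were 4 genes for myelin over all donors, 0 in healthy (limma, 137 at an unadjusted p under 0.05) and 0 in MS donors (233), 916 for bexarotene over all donors, 430 in healthy and 343 in MS donors, 0 for the difference of the bexarotene effects (240), 1112 for myelin with bexarotene against control and 494 for MS against healthy with myelin; 1 list passed camera for myelin, against 2. With the donor as a random block the counts were 16 for myelin in healthy and 7 in MS donors, and 1 for the difference of the bexarotene effects. The block changed no other count by more than 1.5 times.

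With only the 8 arrays compared, MS against healthy gave 126 genes in control, 18 with myelin and 156 with bexarotene, and MS with bexarotene against healthy myelin 653. These fits had fewer arrays and no donor block. Leaving out only the block, with every array kept, gave 730, 494, 1030 and 1512 genes in these comparisons in turn. With the block and every array the counts were 996, 823, 1233 and 1773. Most of each fall therefore came with the use of fewer arrays, and the reason for that was not tested. The stricter filter gave 11 genes for the difference of the bexarotene effects. All probe sets gave 14 for myelin in MS donors, 2 for the difference of the bexarotene effects and 1950 for MS against healthy with bexarotene. Array weights gave 81 for myelin over all donors, 12 for the difference of the bexarotene effects, and 1540 and 1324 for MS against healthy in control and with myelin. Without the filter the agreement of the diagnoses across genes was 0.23 for myelin and 0.81 for bexarotene. With an estimated correlation camera passed 0 lists for myelin (2 with the preset one), 2 for bexarotene (7), and 1, 1 and 0 for MS against healthy in control (4), with myelin (6) and with bexarotene (5).

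Leaving out 1 donor at a time gave 32 to 49 genes for myelin over all donors, 16 to 31 in healthy and 8 to 25 in MS donors, 0 to 8 for the difference of the bexarotene effects, and 415 to 1067, 335 to 923 and 472 to 1350 for MS against healthy in control, with myelin and with bexarotene. Correlations across genes were 0.21 to 0.37 between diagnoses for myelin, 0.82 to 0.86 for bexarotene, −0.038 to 0.19 for healthy myelin against MS bexarotene and −0.042 to 0.025 for MS myelin against healthy bexarotene.

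Changes close to 0 that had not passed changed sign. ABCG1 was 0 after centring and 0.02 after quantile normalization for the difference of the myelin effects, 0.01 after centring for MS against healthy in control and with myelin, and with array weights 0 for myelin in MS donors and 0.06 for the difference of the myelin effects. RXRA was 0.01 after quantile normalization for the difference of the bexarotene effects. Without 1 donor, ABCG1 was −0.07 to 0.02 for myelin over all donors, −0.10 to 0.07 in healthy and −0.11 to 0.02 in MS donors, −0.10 to 0.08 for their difference, and −0.10 to 0.10 and −0.11 to 0.05 for MS against healthy in control and with myelin. RXRA was −0.08 to 0.06 for myelin in healthy donors, −0.18 to 0.02 for bexarotene in MS donors and −0.12 to 0.08 for the difference of the bexarotene effects, and RXRB −0.07 to 0.06 for myelin in healthy donors, −0.06 to 0 for bexarotene over all donors and −0.02 to 0.10 in MS donors.

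For the number of arrays, the precision of every comparison is limited by 4 donors per diagnosis, and genes under the 40th percentile of an array's values were tested only without the filter.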

Other observations

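No test in this part was chosen after its result was seen. Most of the lists not yet described for bexarotene held genes that passed, but none of these lists passed camera with an estimated correlation. Of 13 heat shock genes 6 rose (7 adjusted over the list alone), with the chaperone cofactor DNAJB1 at 0.66 ± 0.09; the camera call (0.014) was lost with an estimated correlation (adjusted p = 0.45). Of 13 oxidative stress and iron genes 4 rose and 4 fell (5 and 4 adjusted over the list alone), with the haem oxygenase HMOX1 at 0.88 ± 0.07 (camera 0.84). Of 19 genes of cholesterol synthesis and uptake 3 rose and 4 fell, with the sterol carrier STARD4 at 0.63 ± 0.05 and the squalene epoxidase SQLE at −0.40 ± 0.05 (camera 0.92). Of 17 antigen presentation genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with CD80 at 0.89 ± 0.08 and CD1D at 0.69 ± 0.07 (camera 0.93 upward, median −0.02, mean 0.06). Of 18 genes of the unfolded protein response 3 rose and 3 fell, with CEBPB at 0.65 ± 0.05 (camera 0.92). Of 16 glycolysis genes 4 fell (camera 0.39), of 20 oxidative phosphorylation genes 3 rose (camera 0.13), and of 12 cell cycle genes 3 rose and 1 fell (camera 0.68). Of 12 extracellular matrix genes 2 rose and 4 fell, with the membrane protease MMP14 at −0.51 ± 0.07 (camera 0.49). The 7 metallothioneins had a median of 0.06 (camera 0.42).

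Of 12 T cell markers 2 rose with bexarotene, including the adaptor LAT (0.34 ± 0.05; camera 0.72 upward, median −0.01, mean 0.03), and of 9 B cell markers 2 rose (camera 0.18). Of 9 platelet markers 2 rose, including P-selectin SELP (0.88 ± 0.11; camera 0.5), of 10 neutrophil markers 1 rose (camera 0.68), and of 8 NK cell markers 1 rose and 1 fell (camera 0.92 upward, median −0.01, mean 0.10). Of 8 dendritic cell markers 2 rose and 1 fell (3 and 1 adjusted over the list alone), with the chemokine receptor CCR7 at 0.61 ± 0.08 and IL3RA at −0.60 ± 0.07 (camera 0.62). Of 9 neuron and astrocyte markers 1 rose and 1 fell, the latter being the glutamate transporter SLC1A3 at −1.44 ± 0.07 (camera 0.97 upward, median 0.01, mean −0.11). Medians were 0.04 over 3 erythroid markers (camera 0.8) and 0.02 over 7 oligodendrocyte markers (mean −0.02, camera 0.97 upward). Without the donor block CCR7 (adjusted p = 0.17), IL3RA (0.31) and MMP14 (0.35) did not pass.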
